A study of Mus musculus with 4 samples.

How the data were processed

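The 4 libraries came as count matrices, and per the submitters' processing notes the authors had made these counts of unique molecules with Cell Ranger 6.1.2 against mm10 before they were deposited. The same notes name Seurat 4.0.6 without its role, and how barcodes were chosen is not given in the sources used here. All 4 matrices listed the same 32285 features, of which 32235 (99.8%) had an identifier in the GENCODE vM21 annotation used for positions, a copy whose build may differ from that of the authors. Counts were used as integers, with no correction for free RNA and no integration of libraries in the results called main.

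Cells were retained with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs, limits fixed before the data were examined. Doublets were called by Scrublet through scanpy. The tool's own threshold marked 0 cells in 1 library, so 1 threshold (0.217), the median of those in the 3 libraries where it marked at least 0.5% of cells, was used for all, a choice made after the data were seen. It marked 503, 707, 314 and 346 doublets, which were left out.

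Counts were scaled to the same total per cell and log transformed. From 2000 variable genes, leaving out Nipbl, S phase, G2 and M phase, mitochondrial and ribosomal protein genes, 30 principal components and 15 neighbours were computed on 61346 cells. Leiden clustering with shared-neighbour weights (resolution 1, seed 0) gave 31 clusters, against 20 at resolution 0.5 and 46 at resolution 2. Classes were named from 15 marker lists fixed before the data were examined. A cluster took a name where at least 3 markers of a list stood at least 1 log2 unit above the other clusters, each in at least 10% of its cells. Among lists that met this, the one with the highest mean was taken, unless markers of another list were more frequent among the 10 leading genes. These naming limits were set after the clusters were seen. Cluster 24 (0.0440%, 0.0513%, 2.11% and 2.18% of cells) met the limits as mature neutrophil-like but had Apoc2, Arhgef37 and Apoe among its leading genes, the first 2 also leading monocyte-like cluster 2 and the last macrophage-like cluster 6, and was left unnamed after its leading genes were seen. Class names carry "-like" because they rest on transcripts alone. In all 11 classes were named, and 7 had the 50 cells per library needed to be tested within.

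Raw counts were summed per library over all cells and within each class. Tests used edgeR 4.0.16 quasi-likelihood fits with robust settings, TMM factors, filterByExpr and Benjamini-Hochberg adjustment at 0.05, with 2 libraries against 2. Standard errors were the log2 fold change divided by the square root of F. DESeq2 1.42.0 was the second tool. Cell numbers per class and cluster were tested by edgeR without TMM. Interactions between classes used edgeR with a term per library. Single values per library were compared by exact permutation over the 6 possible regroupings, which cannot give p below 0.333. No samples were left out by any outlier test, because 2 per group do not allow one.

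Gene lists, 28 in number, were fixed before the data were examined and tested by limma camera (3.58.1) with a preset correlation of 0.01, beside the correlation estimated from the data and fry. With 4 libraries the test with an estimated correlation rests on few residual degrees of freedom and has little power. It called no list in any set of cells, so failing it does not tell a changed list from an unchanged one. The lists were cohesin and loop extrusion; primary granule; secondary and tertiary granule; neutrophil maturation; stem and early progenitor; myeloid and erythroid transcription factors; monocyte; macrophage; conventional dendritic cell; plasmacytoid dendritic cell; lymphoid progenitor and B cell; T, NK and innate lymphoid cell; erythroid; megakaryocyte; basophil and mast cell; eosinophil; stromal; inflammatory cytokine and NF-kB response; interferon response; p53 response; S phase; G2 and M phase; nuclear envelope and lamina; lysosome and uptake; immediate early and heat shock; glycolysis and hypoxia; mitochondrially encoded; and ribosomal protein.

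Genes were named in the text by a rule fixed before the data were examined. It took Nipbl and the cohesin list, and the 10 called genes with the largest rise and the 10 with the largest fall (5 each in the smaller classes) with a mean of at least 10 CPM and no overlap between gates, and up to 4 called members of each list. Which of these the text prints was chosen after their values were seen.

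For phase calls and depth checks each cell was thinned to 3900 UMIs, the 10th percentile rounded down. This left out 524, 3112, 1431 and 617 shallower cells, so thinned results rest on the deeper cells of ATTO low/negative replicate 2 above all. In the basophil/mast cell-like class thinning left only 43 and 60 cells in the ATTO high libraries. Phases were scored with scanpy on the S and the G2 and M phase lists.

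Alternatives chosen after the data were seen were the best shared cluster of a class alone, subtraction of free RNA, clustering without the 6708 genes called in at least 2 classes, both neutrophil classes counted together, and gene lists on thinned cells, on the same mix of clusters and on the first pair of these. Free RNA was estimated per class and library as the median ratio of class to library level over markers of other classes (2.77% to 15.1% of class counts) and subtracted as that share of the library profile. On count tables made from these data with 200 genes changed, the edgeR test recovered 82% of 2-fold changes in all cells, 80% in immature neutrophil-like and 90% in monocyte-like cells. False calls were 3.31%, 2.27% and 6.41% of all calls. Far more genes were called in the data than were changed there (10831 of 15057 over all cells). These rates therefore do not cover a shift of most genes. The first design of the share simulation was replaced after its result was seen, because shares cannot rise alone.

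Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3.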

Results

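The series asks how the machinery of chromatin loop extrusion relates to the shape of the nucleus, per its title. These libraries profiled mouse bone marrow progenitors in which Nipbl was targeted for editing. Nipbl encodes the loader of cohesin, the ring complex that extrudes chromatin loops. Marrow of C57BL/6 mice aged 6 to 10 weeks was depleted of mature cells, electroporated with Cas9 and a guide RNA against NIPBL, and cultured for 72 h with SCF and FLT3, each at 25 ng/mL, in medium with 10% serum. Cells were then sorted by their ATTO signal into a high gate and a low or negative gate. ATTO is a family of fluorescent dyes, and the labels do not say which component carried the dye. Each gate gave 2 droplet-based libraries, replicates 1 and 2, so every comparison set 2 ATTO high libraries against 2 ATTO low/negative libraries. Cells without the guide were not analysed here. The labels do not say whether the replicates came from separate cultures or animals, so the p-values measure only the spread between libraries, which may be technical.

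The ATTO low/negative libraries held 15712 and 16644 barcodes with 149415217 and 114926585 UMIs, and the ATTO high libraries 15947 and 17915 barcodes with 155495205 and 216205425 UMIs. Below, values of single libraries follow this order: ATTO low/negative replicates 1 and 2, then ATTO high replicates 1 and 2. After filtering, 13649, 15598, 15152 and 16947 cells were retained. Their median depths were 9104, 5984, 8008 and 10075 UMIs, which did not separate the gates (two-sided exact permutation p = 0.667, n = 2 per gate). Depth did separate the gates in each of the 7 classes tested within (exact p = 0.333 for each). It was higher in ATTO high in 6 of them, for example 5730, 3827.5, 8350 and 11183 UMIs in immature neutrophil-like and 12037, 8171, 18033 and 23176 in neutrophil progenitor-like cells, and lower in basophil/mast cell-like cells. The median share of mitochondrial UMIs was 4.01%, 3.81%, 1.70% and 1.48%, and the 20 most abundant genes took 14.4%, 15.2%, 30.8% and 30.6% of the UMIs. Both measures separated the gates, with an exact permutation p of 0.333, the smallest that 2 libraries against 2 can give.

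Nipbl (ENSMUSG00000022141, chromosome 15, 8290617 to 8444463 on the minus strand of mm10) was read first, as the targeted gene. A count of 3′ tags does not show whether cells were edited, and the labels do not give the edited site. Over all cells Nipbl rose in ATTO high by 0.36 ± 0.06 (log2 fold change ± standard error, as throughout; adjusted p = 7.7e-04, edgeR quasi-likelihood with Benjamini-Hochberg), from 109 and 113 CPM to 143 and 141 CPM. With the same number of cells of each cluster drawn from every library, the change was 0.0064 and no longer passed. Within classes Nipbl passed in the monocyte-like class (0.21 ± 0.06, edgeR adjusted p = 0.016; 132, 143, 162 and 155 CPM). That call ended without ATTO low/negative replicate 1 (0.15), without ATTO high replicate 1 (0.18), in cluster 2 alone (0.10) and with coarser clusters (0.018). In the other 6 classes tested, the change ran from −0.12 in conventional dendritic cell-like to 0.24 in basophil/mast cell-like cells, none past the threshold. Of these, neutrophil progenitor-like cells passed in cluster 12 alone (0.21), and immature neutrophil-like cells with coarser clusters (0.25) and without the low-count filter (0.18). After thinning every cell to 3900 UMIs, 36.3%, 36.2%, 39.4% and 38.9% of cells held a Nipbl UMI. A single UMI at that depth equals 256 CPM, above the level of the gene, and no class lacked Nipbl, so no change was read from these shares.

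Mature neutrophil-like cells made up 26.1% and 31.2% of the ATTO high libraries and 0.154% and 0.192% of the ATTO low/negative libraries, a difference of 7.36 ± 0.34 (edgeR on cell numbers, adjusted p = 1.6e-16; higher in both ATTO high libraries). Immature neutrophil-like cells, named by secondary granule genes, rose from 9.09% and 14.5% to 36.1% and 30.3% (1.49 ± 0.24), and macrophage-like cells from 0.271% and 0.346% to 7.33% and 10.1% (4.81 ± 0.49). T, NK and innate lymphoid cell-like cells were few, with 2, 7, 31 and 30 cells, and also rose (2.60 ± 0.76). The other classes fell. Stem/progenitor-like cells went from 3.96% and 4.20% to 0.158% and 0.148% (−4.73 ± 0.10), neutrophil progenitor-like cells from 22.0% and 20.6% to 4.23% and 3.38% (−2.48 ± 0.24), and plasmacytoid dendritic cell-like cells from 14.7% and 13% to 3.98% and 3.48% (−1.90 ± 0.20). The name stem/progenitor-like rests on cluster 16 alone, in which 3 of 12 markers met the naming limits, none among its leading genes. In the cluster named megakaryocyte-like 8 of these 12 met them. With finer clusters a cluster sharing leading genes with cluster 16, among them Ccnd2, Bcl2 and Sox4, was named plasmacytoid dendritic cell-like (864, 1006, 43 and 43 cells). Basophil/mast cell-like (−1.82 ± 0.20), monocyte-like (−1.19 ± 0.24), megakaryocyte-like (−1.20 ± 0.55) and conventional dendritic cell-like cells (−0.47 ± 0.10) fell too. The 3 clusters left unnamed fell when pooled (−1.70 ± 0.09) but did not change alike. Cluster 8 fell (−4.17 ± 0.34), cluster 24 rose (5.46 ± 0.28), and cluster 30 did not pass (0, 33, 9 and 3 cells).

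The share test called all 12 classes, the pooled unnamed clusters counted as 1 of them, and 29 of 31 clusters. On simulated cell numbers with 4 raised classes it also called 59.4% of the classes that had not been raised, since shares add up to a whole, so a fall of one class is not independent of the rise of another. When clusters were built without the genes that differed within classes, the rise of immature neutrophil-like cells (0.45 ± 0.45) and the fall of conventional dendritic cell-like cells (−0.27) no longer passed. In that clustering 70.3% of cells kept their class, and the name mature neutrophil-like covered 1.21%, 0.994%, 43.9% and 46.7% of cells. The value for immature neutrophil-like cells may therefore in part reflect renamed cells. The name megakaryocyte-like passed to only 41 cells (1, 0, 15 and 25; 4.88), with leading genes of the former class, among them Pf4, Itga2b and F2r. A larger cluster, also with leading genes of that class, among them Pf4 and Hlf, was named stem/progenitor-like (242, 351, 113 and 69 cells). The value 4.88 is therefore no rise of the same set of cells. Mature neutrophil-like cells (5.36 ± 0.23) and both neutrophil classes together (2.07 ± 0.37) still rose. Stem/progenitor-like cells still fell (−3.73 ± 0.34) but took in more cells (15.4%, 18.3%, 1.51% and 1.03%), and neither coarser nor finer clusters gave a class of that name. With coarser clusters the conventional dendritic cell-like change was 0.082, and with finer clusters the monocyte-like change was −0.25, neither past the threshold. Calls ended without ATTO high replicate 1 or 2 for T, NK and innate lymphoid cell-like (2.50 and 2.70), basophil/mast cell-like (−1.82 and −1.83) and megakaryocyte-like cells (−1.5 and −0.95). Calls ended without ATTO low/negative replicate 1 (−0.43) or 2 (−0.50) for conventional dendritic cell-like cells, and without ATTO low/negative replicate 2 for megakaryocyte-like cells (−0.93).

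**Figure D1:**
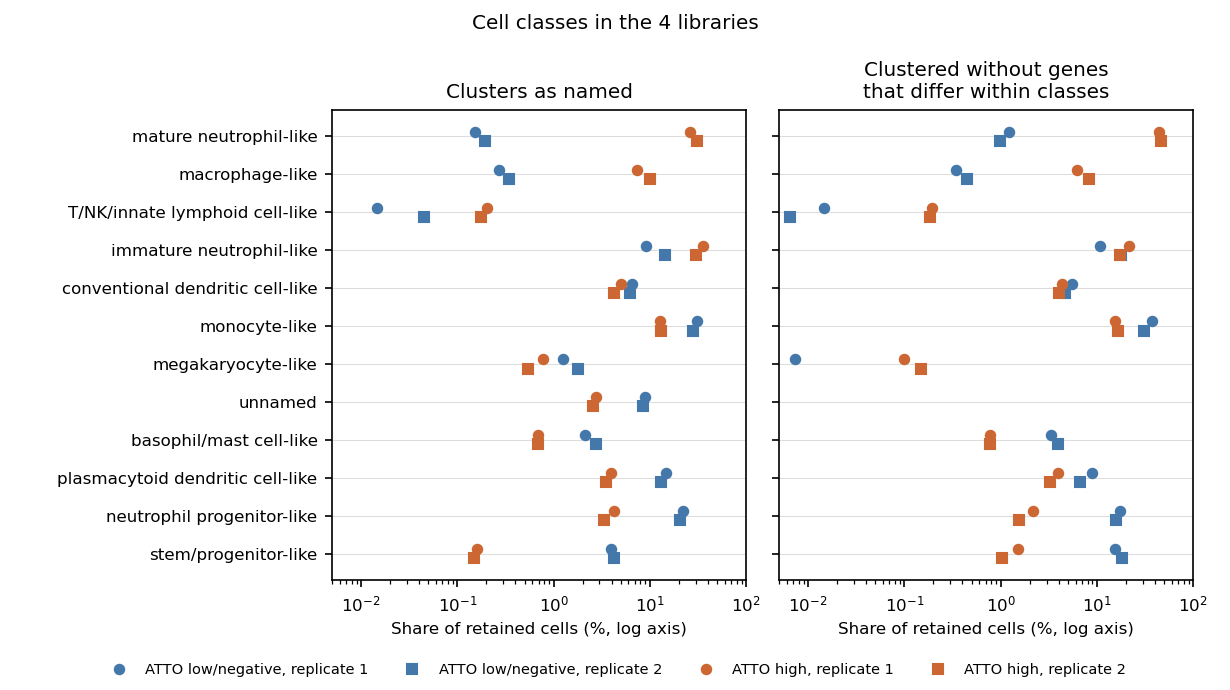
Share of retained cells (%, log axis) in each class, one point per library, for the clusters as named (left) and for clusters built without the genes that differed within classes (right). Mature neutrophil-like and macrophage-like cells lie to the right in ATTO high in both panels; a share of 0 (megakaryocyte-like, ATTO low/negative replicate 2, right) is not drawn, and the right panel has no unnamed clusters.

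Summed over all cells, ATTO high libraries held more transcript of neutrophil maturation, secondary and tertiary granule and macrophage genes and less of S phase, primary granule and ribosomal protein genes. Mmp9, a gelatinase of neutrophil granules, rose by 6.82 ± 0.27 (adjusted p = 1.4e-05, edgeR quasi-likelihood with Benjamini-Hochberg; 2.51, 4.14, 334 and 408 CPM). The protease inhibitor Stfa2l1 rose by 6.44 ± 0.27, Fpr1, a receptor for bacterial formyl peptides, by 6.39 ± 0.27, and Retnlg, a secreted product of mature neutrophils, by 6.36 ± 0.27. Slfn4 (5.84 ± 0.28), the complement receptor C3ar1 (5.58 ± 0.40), the retinol dehydrogenase Dhrs9 (5.38 ± 0.18), the cytokine Il1b (5.35 ± 0.39), the itaconate enzyme Acod1 (5.20 ± 0.33) and Slfn1 (5.13 ± 0.24) followed. The largest falls were in the cyclophilin Ppic (−2.44 ± 0.15), the myeloperoxidase gene Mpo (−2.44 ± 0.14; 1178, 1037, 229 and 179 CPM), the mucin Muc13 (−2.42 ± 0.10), Rangrf (−2.36 ± 0.08), the granule protease Ctsg (−2.17 ± 0.11), the serine synthesis enzyme Phgdh (−2.17 ± 0.10), Abhd14a (−2.15 ± 0.09), Scin (−2.15 ± 0.18), the uracil glycosylase Ung (−2.11 ± 0.08) and the mast cell protease Cpa3 (−2.06 ± 0.23). In all, 10831 of 15057 genes passed, 5470 higher and 5361 lower. With the same number of cells of each cluster drawn from every library, 3927 cells from each, 3939 of 13320 passed and 1142 of the genes called before had the opposite sign. Under that mix Mmp9 (1.92), Retnlg (1.11), Slfn4 (2.38), Il1b (0.97), Acod1 (1.38) and Cpa3 (−0.80) no longer passed, and Cpa3 also lost its call without ATTO low/negative replicate 2 (−1.98). For each gene named here and below as risen or fallen, both ATTO high libraries lay on the same side of both ATTO low/negative libraries.

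Of the 16 cohesin and loop extrusion genes, 6 rose, 7 fell and 3 did not pass over all cells (camera adjusted p = 0.842; adjusted p = 0.961 with an estimated correlation). Smc3, a core subunit of the ring, fell by 0.81 on the log2 scale (194, 203, 122 and 104 CPM) and kept its call under every alternative run. The cohesin acetyltransferase gene Esco1 rose (0.87 ± 0.06), as did Stag2 (0.43 ± 0.05), the loader partner Mau2 (0.39 ± 0.06), the release factor Wapl (0.21 ± 0.06) and Rad21 (0.17 ± 0.06). Cdca5 (−0.54 ± 0.11), Pds5b (−0.52 ± 0.08), Hdac8 (−0.45 ± 0.09), Smc1a (−0.41 ± 0.09), the boundary factor Ctcf (−0.24 ± 0.08) and Pds5a (−0.16 ± 0.06) fell. With the same mix of clusters the changes of these genes other than Smc3 and Rad21 lay between −0.10 (Smc1a) and 0.16 (Esco1) and did not pass, and that of Pds5a turned positive (0.0081). The calls of Wapl, Rad21, Ctcf and Pds5a ended without ATTO low/negative replicate 1 (0.17, 0.16, −0.28 and −0.18) or replicate 2 (0.23, 0.17, −0.22 and −0.16), and that of Rad21 also without ATTO high replicate 1 (0.13) on thinned cells (0.0068) and at the stricter mitochondrial limit (0.14).

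Neutrophil and phagocyte lists rose over all cells. All 18 neutrophil maturation genes (median 2.65) and all 16 secondary and tertiary granule genes (2.53) rose, as did all 10 macrophage genes (4.42), among them the complement gene C1qa (5.07 ± 0.47), and all 18 lysosome and uptake genes (1.74), among them Gpnmb (3.48 ± 0.10) and the scavenger receptor Cd36 (6.19 ± 0.21). Among conventional dendritic cell genes 11 of 12 rose (2.05), including the MHC class II gene H2-Eb1 (2.40 ± 0.15), the chemokine receptors Xcr1 (4.39 ± 0.34) and Ccr7 (2.98 ± 0.21) and the lectin Cd209a (2.17 ± 0.14). Of the inflammatory cytokine and NF-kB genes 19 of 20 rose (1.99), of the interferon response genes 17 of 18 (2.32), of the immediate early and heat shock genes 11 of 13 (1.52) and of the T, NK and innate lymphoid genes 5 of 6 (2.88). Camera called these 9 lists higher (adjusted p from 1.04e-06 to 0.0419), none of them past the threshold with an estimated correlation (adjusted p = 0.706 with an estimated correlation for each). Here and below, that second test had little power with 4 libraries and passed no list in any set of cells. The T, NK and innate lymphoid call ended without ATTO high replicate 2 (median 2.92), on thinned cells (3.07) and with the same mix of clusters (0.42), and its median was 4.56 without ATTO low/negative replicate 2. With the same mix of clusters the medians were 0.52 for maturation, 0.46 for secondary granule, 0.69 for macrophage, 1.07 for dendritic cell, 0.61 for interferon, 0.48 for inflammatory, 0.49 for immediate early and 0.46 for lysosome genes in all cells, all still called by camera.

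The S phase, ribosomal protein, mitochondrially encoded and primary granule lists fell over all cells. All 25 S phase genes fell (median −1.31), among them the helicase genes Hells (−1.69 ± 0.09; 115, 119, 39.5 and 32.9 CPM) and Mcm2 (−1.47 ± 0.07). Of 83 ribosomal protein genes 80 fell and 2 rose (−0.80), with Rps2 at −1.33 ± 0.06, and 12 of 13 mitochondrially encoded genes fell (−0.54), with mt-Nd3 at −0.92 ± 0.06. Of 10 primary granule genes 8 fell and 1 rose (−1.17), among them Prtn3 (−1.74 ± 0.09) and Elane (−1.58 ± 0.09), proteases packed at the promyelocyte stage. Camera called these 4 lists lower (adjusted p from 4.62e-15 to 0.011; adjusted p = 0.706 with an estimated correlation for each). With the same mix of clusters their medians in all cells were −0.26, −0.27, −0.21 and −0.41, still called.

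The remaining 14 lists did not pass camera over all cells, and counts of their members were also mixed. Stem and early progenitor genes split, 5 higher and 9 lower of 16 (Cd34 −1.53 ± 0.09, Ly6a 1.42 ± 0.06), as did transcription factors, 8 and 8 of 16 (Myc −1.83 ± 0.07, Gata2 −1.40 ± 0.17), p53 response genes, 11 and 5 of 19 (Trp53inp1 2.53 ± 0.08, Fas 2.06 ± 0.12), and nuclear envelope and lamina genes, 6 and 4 of 14 (Syne2 1.61 ± 0.12 and Sun2 1.11 ± 0.05, which link the nucleus to the cytoskeleton). Monocyte genes counted 9 higher and 3 lower of 14 (Ctss 1.60 ± 0.11, Fn1 1.27 ± 0.11), glycolysis and hypoxia genes 8 and 3 of 13 (Pdk1 −1.05 ± 0.07), lymphoid progenitor and B cell genes 5 and 3 of 8, megakaryocyte genes 3 and 1 of 7, erythroid genes 1 and 3 of 11, eosinophil genes 2 and 2 of 5, plasmacytoid dendritic cell genes 2 and 4 of 7 (Ccr9 1.27 ± 0.10), and basophil and mast cell genes 1 and 6 of 12. Of 35 G2 and M phase genes 6 were higher and 5 lower (1 and 0 adjusted over the list alone). For every other list over all cells, the counts adjusted over the list alone were the same. Median, mean and test differed in sign for the transcription factor, erythroid and eosinophil lists. Too few stromal genes were measured to test.

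**Figure D2:**
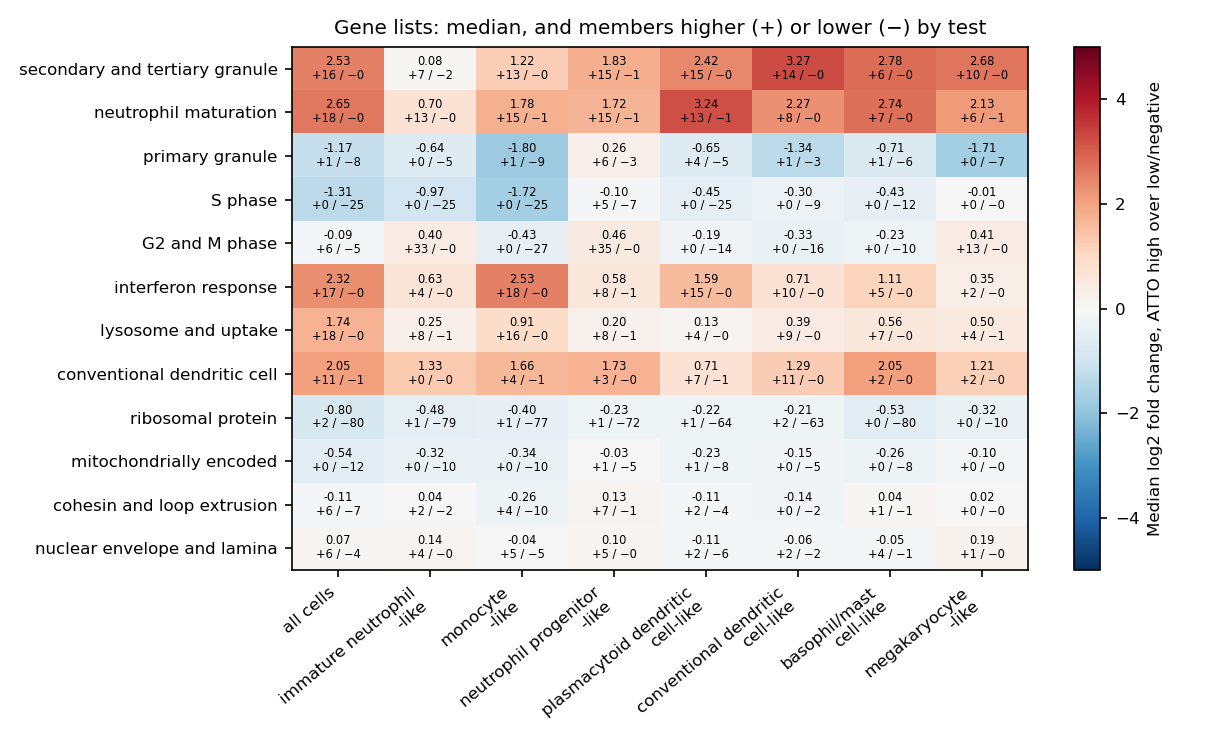
Median log2 fold change of ATTO high over ATTO low/negative (colour and upper number) and members higher (+) and lower (−) by the edgeR test (lower numbers) for 12 of the gene lists, over all cells and in each class tested. The secondary granule row is red in all cells (2.53) and 0.08 in immature neutrophil-like cells, and the ribosomal protein row is negative in every column.

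Within the immature neutrophil-like class, genes of later neutrophils rose and genes of DNA replication fell in ATTO high. Mmp9 rose by 2.51 ± 0.07 (adjusted p = 2.2e-17, edgeR quasi-likelihood with Benjamini-Hochberg; 35.6, 38.8, 221 and 205 CPM), Fpr1 by 2.23 ± 0.14, the ectoenzyme gene Bst1 by 2.04 ± 0.08, Slfn4 by 1.76 ± 0.12 and the kinase gene Bmx by 1.74 ± 0.14. Basp1 (2.24 ± 0.13), the collagenase Mmp8 (2.16 ± 0.28), the receptor Gpr27 (2.15 ± 0.15), Stfa2l1 (2.05 ± 0.30) and the cystine transporter Slc7a11 (1.72 ± 0.24) also rose. The replication licensing gene Cdc6 fell (−1.57 ± 0.10), with the helicase subunit Mcm6 (−1.44 ± 0.07; 99.5, 88.6, 35.4 and 33.7 CPM), Pole2 (−1.36 ± 0.13), the chromatin assembly factor Chaf1b (−1.36 ± 0.11), Hells (−1.32 ± 0.08) and Gins2 (−1.25 ± 0.10). Ifitm1 (−1.78 ± 0.18), C1qbp (−1.52 ± 0.14), Syce2 (−1.28 ± 0.09) and Myl10 (−1.25 ± 0.09) completed the largest falls. Of 11608 genes 3426 passed, 1717 higher and 1709 lower. The class held different clusters in the gates: cluster 9 was mostly ATTO low/negative (4.90%, 8.73%, 2.05% and 1.31% of cells), cluster 0 mostly ATTO high (1.13%, 0.622%, 19.2% and 16.4%), and cluster 3 was the best shared. In cluster 3 alone 1391 genes passed, and Mmp9 (4.74), Basp1 (1.45), Mmp8 (2.61), Gpr27 (2.03), Stfa2l1 (1.87) and Slc7a11 (0.65) did not. Without ATTO low/negative replicate 1 the call count was 2224, and Mmp8 (1.99), Stfa2l1 (1.84) and Slc7a11 (1.88) lost their calls, the first and last also without replicate 2 of that gate (2.39 and 1.56). With free RNA subtracted, Mmp8 (2.17), Ifitm1 (−1.48) and C1qbp (−0.49) no longer passed, nor did Mmp8 without the low-count filter (2.20).

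All 25 S phase genes fell in the immature neutrophil-like class (median −0.97), 21 of them in cluster 3 alone (−0.58). Among G2 and M phase genes 33 of 35 rose (34 adjusted over the list alone; median 0.40), led by Cenpf (0.93 ± 0.06) and the mitotic ubiquitin enzyme Ube2c (0.88 ± 0.06). On cells thinned to one depth that median was −0.20, with 0 members higher and 2 lower by edgeR, and Cenpf (0.30) and Ube2c (0.26) did not pass. Cluster 17 of the class, itself led by Cenpf and Ube2c, held 45, 48, 454 and 430 cells. Neutrophil maturation genes rose in 13 of 18 (0.70), including Fpr2 (1.56 ± 0.08) and the lectin Clec4d (1.69 ± 0.13), and the secondary and tertiary granule list did not pass (7 higher, 2 lower of 16; 0.077), with the early gene Fcnb lower (−0.77 ± 0.05). Primary granule genes fell in 5 of 10 (−0.64), with Prtn3 at −0.83 ± 0.06, basophil and mast cell genes in 6 of 7 (6 lower and 1 higher adjusted over the list alone; −2.19), mitochondrially encoded genes in 10 of 13 (11 adjusted over the list alone; −0.32) and ribosomal protein genes in 79 of 83 (−0.48), with Rps2 at −0.70 ± 0.06. Inflammatory genes rose in 7 of 16 (0.88), among them the lectin receptor Clec4e (1.22 ± 0.10) and the interleukin 1 antagonist Il1rn (1.02 ± 0.11), and the list median was 0.46 without ATTO high replicate 2. Camera called each of these lists other than the secondary granule list (adjusted p from 1.18e-26 to 0.004; adjusted p = 0.583 with an estimated correlation for each). In cluster 3 alone the maturation median was 0.44 and the inflammatory median 0.51, and on thinned cells the S phase, maturation, primary granule, inflammatory and mitochondrial medians were −1.48, 1.32, −1.29, 1.33 and −0.58. With free RNA subtracted, the primary granule (−0.040) and basophil (−0.95) calls ended. Basophil and mast cell genes were themselves among the markers used for that subtraction. Macrophage (3 of 5 higher, 5 adjusted over the list alone; 1.94), dendritic cell (0 of 7; 1.33), interferon (4 of 16 higher, 6 adjusted over the list alone; 0.63) and lysosome genes (8 higher and 1 lower of 14, 9 and 1 adjusted over the list alone; 0.25) were called higher as lists, and each call ended without ATTO low/negative replicate 1 (medians 2.14, 1.07, 0.54 and 0.21; lowest adjusted p = 0.583 with an estimated correlation), the dendritic cell call also without replicate 2 of that gate (1.45). Without the latter library the interferon and lysosome medians were 1.06 and 0.50, without ATTO high replicate 2 the macrophage median was 1.04, and in cluster 3 alone the lysosome median was −0.037. Of the 16 cohesin genes Rad21 (0.28 ± 0.06) and Sgo1 (0.43 ± 0.08) rose, and Smc3 (−0.34 ± 0.06) and Smc1a (−0.24 ± 0.06) fell, the rest not passing. On thinned cells Rad21 (−0.090) and Sgo1 (−0.25) turned negative without passing, in cluster 3 alone Sgo1 did not pass (0.23), and Smc1a lost its call without ATTO low/negative replicate 2 (−0.17) or ATTO high replicate 2 (−0.19). Median, mean and test differed in sign for the lymphoid, megakaryocyte and eosinophil lists.

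Within the monocyte-like class, interferon response and monocyte genes rose, and primary granule and S phase genes fell. All 18 interferon response genes rose (median 2.53), among them Rsad2, an antiviral enzyme (4.07 ± 0.69, adjusted p = 0.0336, edgeR quasi-likelihood with Benjamini-Hochberg; 6.73, 8.32, 75.0 and 173 CPM), and Ifit3 (3.54 ± 0.41). The chemokine genes Ccl5 (4.82 ± 0.29) and Ccl4 (4.49 ± 0.56), the lipase Pla2g7 (3.44 ± 0.08; 25.8, 22.6, 269 and 259 CPM), Ifit1bl1 (4.33 ± 0.57), Ifi205 (3.69 ± 0.60) and Ifit3b (3.42 ± 0.54) were among the largest rises, with the neutrophil genes Mmp9 (6.87 ± 0.45; 0.114, 0.331, 19.4 and 28.8 CPM) and Retnlg (5.95 ± 0.43). Mpo (−2.54 ± 0.16), Dtl (−2.40 ± 0.11), Elane (−2.34 ± 0.05; 1067, 1006, 204 and 206 CPM), Cdca7 (−2.26 ± 0.08), Prtn3 (−2.22 ± 0.05), Hells (−2.22 ± 0.07), Ctsg (−2.21 ± 0.09), Cdc6 (−2.21 ± 0.11), the cyclin Ccne2 (−2.19 ± 0.08) and the progenitor factor Myb (−2.18 ± 0.11) fell most. Of 12289 genes 6894 passed, 3526 higher and 3368 lower. Cluster 1 held most of the class in ATTO low/negative (16.8%, 14.7%, 0.904% and 0.808% of cells), and cluster 2 was the best shared (6.88%, 7.35%, 8.56% and 8.54%). In cluster 2 alone 1816 genes passed, 611 genes called in the class had the opposite sign, and the interferon median was 0.42, with 4 members higher and 1 lower. There Rsad2 (0.81), Ifit3 (0.60), Retnlg (3.36), Mpo (−2.83), Cdc6 (−0.85) and Ccne2 (−0.65) did not pass. The calls of Rsad2, Ifit3, Ccl4, Ifit1bl1, Ifi205 and Ifit3b each ended without ATTO low/negative replicate 1 (3.91, 3.54, 4.12, 3.91, 3.54 and 3.32) or replicate 2 (4.21, 3.54, 4.87, 4.73, 3.80 and 3.49), and those of Rsad2 (4.07), Ifit1bl1 (4.33), Ifi205 (3.69) and Ifit3b (3.42) also without the low-count filter. Rsad2 did not pass once free RNA was subtracted (3.99).

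Of 14 monocyte genes in the monocyte-like class 11 rose and 1 fell (2 adjusted over the list alone; median 0.67), with the protease Ctss (1.45 ± 0.05), fibronectin Fn1 (1.57 ± 0.07) and Ms4a4c (1.47 ± 0.15) higher. Lysosome and uptake genes rose in 16 of 18 (0.91), among them Gpnmb (2.50 ± 0.13), Msr1 (2.39 ± 0.12) and Cd68 (1.29 ± 0.08), and inflammatory genes in 10 of 17 (1.10), with the receptor Tlr2 at 1.35 ± 0.19. Macrophage genes rose in 4 of 9 (1.81), with Adgre1 at 1.81 ± 0.10, and immediate early genes in 6 of 13 with 1 lower (7 and 1 adjusted over the list alone; 1.09), with Zfp36 at 1.52 ± 0.22. In cluster 2 alone the lysosome, maturation, secondary granule, mitochondrial and ribosomal protein medians were 0.31, 0.76, 0.56, −0.22 and −0.21, the macrophage median was −0.79 and the monocyte (0.19), inflammatory (0.18) and immediate early (0.62) lists lost their calls. Without ATTO low/negative replicate 1 the immediate early median was 0.69. Neutrophil maturation (15 higher, 1 lower of 18; 1.78) and secondary and tertiary granule genes (13 of 16 higher; 1.22) rose, in libraries that were 62.2% and 61.5% neutrophil-like against 9.25% and 14.7%. Subtracting free RNA gave a secondary granule median of 0.61, and the maturation median was 0.95 and its call ended. Both lists share genes with the markers that set the subtracted share, so this outcome was partly fixed in advance. S phase genes fell in all 25 (−1.72), primary granule genes in 9 of 10 with 1 higher (−1.80), stem and early progenitor genes in 8 of 12 with 1 higher (−0.80), basophil genes in 5 of 7 (−1.94), mitochondrially encoded genes in 10 of 13 (11 adjusted over the list alone; −0.34) and ribosomal protein genes in 77 of 83 with 1 higher (78 and 1 adjusted over the list alone; −0.40). The stem call ended in cluster 2 alone (−0.47) and with free RNA subtracted (−0.19). Neutrophil progenitor-like cells, whose markers include Mpo, Elane, Prtn3 and Ctsg, made up 22.0% and 20.6% of ATTO low/negative against 4.23% and 3.38% of ATTO high libraries. Free RNA of those cells may enter the fall of primary granule genes here and in the dendritic cell-like classes. How much it does was not tested. Of 35 G2 and M phase genes 27 fell (−0.43), among them the survivin gene Birc5 (−0.61 ± 0.09). With coarser clusters Birc5 rose (0.42), and the list median was −0.27 without ATTO high replicate 2. Camera called these lists and the interferon list (adjusted p from 6.42e-14 to 0.017; adjusted p from 0.572 to 0.672 with an estimated correlation). The cohesin list did not pass (4 higher, 10 lower of 16; −0.26), with Smc3 (−0.88 ± 0.07) and Smc1a (−0.63 ± 0.08) lower under every alternative run. Median, mean and test differed in sign for 5 lists.

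In the ATTO high gate, neutrophil progenitor-like cells held more transcript of G2 and M phase and secondary and tertiary granule genes and less of monocyte genes. Of 10 primary granule genes 6 rose and 3 fell, and that list did not pass (median 0.26, and −0.12 and called lower in cluster 12 alone). All 35 G2 and M phase genes rose (median 0.46), led by Ube2c (1.07 ± 0.05; 132, 144, 287 and 293 CPM), Nusap1 (0.86 ± 0.06), Cenpf (0.85 ± 0.05) and the mitotic motor Kif11 (0.72 ± 0.05). Secondary and tertiary granule genes rose in 15 of 16 with 1 lower (1.83), among them Cd177 (2.50 ± 0.19) and lactoferrin Ltf (2.57 ± 0.42), and neutrophil maturation genes in 15 of 18 with 1 lower (1.72), among them Retnlg (5.33 ± 0.33). Mmp9 (6.76 ± 0.62) and the inhibitory receptor Lilr4b (2.38 ± 0.35) were the other largest rises. Monocyte genes fell in 12 of 14 with 1 higher (−0.96), including Ms4a6c (−1.36 ± 0.05) and Irf8, a factor that directs monocyte and dendritic cell fates (−1.35 ± 0.06; 143, 145, 59.9 and 52.9 CPM). The integrin Itga1 (−1.37 ± 0.08), the cytokine receptor Il6st (−1.36 ± 0.12), Ifitm1 (−1.33 ± 0.05) and the stem cell antigen Cd34 (−1.31 ± 0.08) fell. Ribosomal protein genes fell in 72 of 83 with 1 higher (73 and 1 adjusted over the list alone; −0.23). Camera called these 5 lists (adjusted p from 1.42e-12 to 1.82e-05; adjusted p = 0.541, and 0.601 for ribosomal protein, with an estimated correlation). Syne1 (1.46 ± 0.07), Syne2 (1.57 ± 0.09) and Sun2 (0.78 ± 0.05) rose, as did Lbr, a lamin receptor of the inner nuclear membrane (0.29 ± 0.05). Of the cohesin genes 7 of 16 rose and 1 fell, Rad21 (0.37 ± 0.05) and Stag2 (0.31 ± 0.05) under every alternative run. In cluster 12 alone the secondary granule and maturation medians were 1.09 and 1.01, and with free RNA subtracted the latter was 0.63. The cohesin (0.13) and nuclear envelope (5 of 14 higher, 4 adjusted over the list alone; 0.10) lists just passed camera (adjusted p = 0.0495 for both, with adjusted p = 0.601 and 0.541 with an estimated correlation), and each call ended without any 1 of the 4 libraries (medians 0.072 to 0.19 and 0.091 to 0.14). Macrophage (1.33), dendritic cell (1.73), interferon (0.58) and lysosome (0.20) lists were also called higher (adjusted p from 0.541 to 0.762 with an estimated correlation), and each call ended without ATTO high replicate 2 (1.23, 1.48, 0.37 and 0.20). Of 11928 genes 5438 passed, 2744 higher and 2694 lower, against 3420 in the best shared cluster, cluster 12. That cluster held 632, 775, 369 and 327 cells of the class, while cluster 15 held 778, 775, 61 and 43 and cluster 23 held 405, 388, 7 and 10. In cluster 12 alone Irf8 (−1.18), Ms4a6c (−1.09) and the monocyte list (−0.33) did not pass, nor did Irf8 with coarser clusters (−0.79). Ltf lost its call without ATTO high replicate 1 (2.64) or 2 (2.50), with doublets kept (1.63) and with free RNA subtracted (3.99), among others, and Mmp9 without ATTO low/negative replicate 2 (7.09).

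In the ATTO high gate, plasmacytoid dendritic cell-like cells held more of the conventional dendritic cell, interferon response and lymphoid progenitor genes. H2-Eb1 rose by 2.36 ± 0.10 (adjusted p = 9.47e-08, edgeR quasi-likelihood with Benjamini-Hochberg; 72.1, 76.7, 340.4 and 420.2 CPM), H2-Aa by 2.03 ± 0.08 and the invariant chain gene Cd74 by 1.95 ± 0.12, in a dendritic cell list with 7 of 11 higher and 1 lower (median 0.71). Stem and early progenitor genes rose in 9 of 11 with 1 lower (0.81), among them Meis1 (1.06 ± 0.08). Of 7 lymphoid progenitor genes 5 rose and 1 fell (2.95), among them the recombination gene Rag2 (2.95 ± 0.36) and the B cell factor Ebf1 (3.31 ± 0.46), and the list call ended without ATTO high replicate 1 (2.05) or 2 (1.94). Class markers rose, namely the homing receptor Ccr9 (2.24 ± 0.19), Ly6d (1.30 ± 0.06) and Siglech (0.52 ± 0.06). Interferon response genes rose in 15 of 18 (17 adjusted over the list alone; 1.59), among them Rtp4 (3.10 ± 0.17) and Oasl2 (2.67 ± 0.15). Tmem108 (4.55 ± 0.22) and Cited4 (4.21 ± 0.24) rose most, with the neutrophil genes Retnlg (7.58 ± 1.22), Mmp9 (7.05 ± 0.61) and AA467197 (4.73 ± 0.60), a leading gene of immature neutrophil-like cluster 0. Ifitm1 (−2.20 ± 0.07; 423, 445, 97.7 and 91.4 CPM), Ctsg (−1.88 ± 0.11), the growth factor binding protein Igfbp4 (−1.76 ± 0.10), Prtn3 (−1.67 ± 0.07) and Fkbp1b (−1.64 ± 0.17) fell most. S phase genes fell in all 25 (−0.45), with Pola1 (−0.67 ± 0.08) and Hells (−0.66 ± 0.07), and ribosomal protein genes in 64 of 81 with 1 higher (65 and 1 adjusted over the list alone; −0.22). Neutrophil maturation (13 higher, 1 lower of 17; 3.24) and secondary granule genes (all 15; 2.42) rose, and with free RNA subtracted their medians were −0.024 and 0.45 and the calls ended. Members of both lists were among the markers used for the subtraction, which lowers them by construction. G2 and M phase genes fell in 14 of 35 (−0.19). That median was −0.33 without ATTO high replicate 1 and −0.089, no longer called, without replicate 2 of that gate. In cluster 10 alone it was 0.23, with 19 members higher, and the interferon, S phase and stem medians were 0.83, −0.22 and 0.50. Camera called these 9 lists (adjusted p from 1.68e-09 to 0.00952; adjusted p from 0.477 to 0.582 with an estimated correlation). Of 11754 genes 4752 passed, 2341 higher and 2411 lower, against 1859 in cluster 10, the best shared, where Ly6d (1.5) and Mmp9 (7.20) did not pass. The class held different clusters in the gates: cluster 22, led by Ccr9, held 96, 131, 306 and 323 cells, cluster 10 held 924, 911, 198 and 165, and cluster 11 held 992, 993, 99 and 102. In cluster 22, 4 of 9 conventional dendritic cell markers met the naming limits. The mix of clusters may therefore enter the rise of those genes in the class. Retnlg and Mmp9 lost their calls without ATTO low/negative replicate 1 (6.91 and 7.19) or 2 (8.34 and 6.94), and AA467197 without ATTO high replicate 1 (4.89) or 2 (4.52). Retnlg also lost its call with doublets kept (4.61) and at the stricter mitochondrial limit (7.51).

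Among conventional dendritic cell-like cells, those of the ATTO high gate held more of their own markers. All but 1 of 12 dendritic cell genes rose (12 adjusted over the list alone; median 1.29), among them the cross-presenting subset markers Xcr1 (4.01 ± 0.50; 1.40, 1.76, 18.0 and 31.7 CPM) and Clec9a (1.80 ± 0.19), Cd209a (1.77 ± 0.26) and Ccr7, the receptor that guides activated dendritic cells to lymph nodes (4.74 ± 0.39). The largest rises also held the costimulatory receptor Tnfrsf9 (5.86 ± 0.33), H2-Eb2 (5.67 ± 0.42) and the chemokine Ccl22 (5.94 ± 0.88). Plac8 (−1.40 ± 0.09; 1499, 1372, 596 and 493 CPM), Igfbp4 (−1.72 ± 0.14), Klrb1f (−1.28 ± 0.14), Spaca9 (−1.25 ± 0.18) and Prtn3 (−1.74 ± 0.23) fell most. Among p53 response genes 9 of 17 rose (10 adjusted over the list alone; 0.37), with the death receptor Fas at 1.63 ± 0.23. S phase genes fell in 9 of 25 (17 adjusted over the list alone; −0.30), ribosomal protein genes in 63 of 83 with 2 higher (68 and 2 adjusted over the list alone; −0.21) and G2 and M phase genes in 16 of 35 (23 adjusted over the list alone; −0.33), among them Ube2c (−0.52 ± 0.12). Secondary and tertiary granule genes rose in 14 of 15 (15 adjusted over the list alone; 3.27), with a median of 0.45 and no call once free RNA was subtracted. That list shares members with the markers used for the subtraction, which lowers it by construction. Camera called these 6 lists (adjusted p from 9.34e-11 to 4.26e-04; adjusted p = 0.387 or 0.448 with an estimated correlation). Cluster 27, with Ccr7 and Ccl22 among its leading genes, held 4, 4, 94 and 100 cells, cluster 26, with Xcr1 and Clec9a among them, 71, 70, 134 and 151, cluster 14 505, 594, 351 and 329, and cluster 19 315, 308, 180 and 142. In cluster 14 alone, the best shared, Ccr7 stood at −0.053, Fas (1.10), Cd209a (2.04) and Prtn3 (−2.70) did not pass, the p53 response median was 0.24, and the G2 and M phase median was 0.051. With coarser clusters Ube2c rose (0.44), and Prtn3 (−2.45) and Ccl22 (5.24) did not pass. Once free RNA was subtracted, Cd209a (1.82), Ccl22 (5.98) and Prtn3 (−2.72) lost their calls. Of 11206 genes 2050 passed, 1259 higher and 791 lower, but 485 without ATTO low/negative replicate 1 and 848 without replicate 2. Ccl22 lost its call without the first (6.54) or the second (5.62), as did Ube2c (−0.50 and −0.55), Spaca9 without the first (−1.06), and Prtn3 without ATTO high replicate 1 (−1.69) or 2 (−1.80); without the latter the G2 and M phase median was −0.17.

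Among basophil/mast cell-like cells, those of the ATTO high gate rose in granzyme Gzmb (1.71 ± 0.11; 124, 145, 437 and 441 CPM), the steroid enzyme Cyp11a1 (1.14 ± 0.19) and the basophil factor Gata2 (0.77 ± 0.10). Ribosomal protein genes fell in 80 of 81 (median −0.53), with Rps2 (−0.74 ± 0.06), Rpl22l1 (−0.85 ± 0.09) and Rpl3 (−0.71 ± 0.07). Immediate early genes rose in 5 of 7 (1.15), with Zfp36 (2.93 ± 0.40), Jun (1.86 ± 0.30) and Junb (1.15 ± 0.19), and inflammatory genes in 7 of 12 (9 adjusted over the list alone; 1.01), with the chemokine Ccl3 (3.06 ± 0.33). S phase genes fell in 12 of 25 (14 adjusted over the list alone; −0.43). Neutrophil maturation genes rose in 7 of 11 (10 adjusted over the list alone; 2.74), with Cxcr2 at 3.59 ± 0.16, and Syne1 rose (2.21 ± 0.15). Camera called these 5 lists (adjusted p from 2.16e-19 to 0.00291; adjusted p = 0.294 with an estimated correlation for each), and the immediate early median was 0.51 without ATTO high replicate 2. On thinned cells the immediate early and S phase medians were 1.72 and −0.65. Of 9219 genes 2389 passed, 1303 higher and 1086 lower, with 1160 without ATTO low/negative replicate 1 and 1584 without replicate 2. The class was shallower in ATTO high (median 3438.5 and 3927 UMIs) than in ATTO low/negative (10268 and 6184), and 941 genes passed on thinned cells. With finer clusters it split into cluster 33 (267, 385, 30 and 22 cells) and cluster 40, led by Cyp11a1 (21, 46, 74 and 94 cells).

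Among megakaryocyte-like cells, those of the ATTO high gate rose in stem cell genes, 7 of 15 (10 adjusted over the list alone; median 0.74), among them Ly6a (2.16 ± 0.15), the stem cell factors Hlf (2.11 ± 0.16; 66.6, 59.7, 289 and 254 CPM) and Mecom (2.0 ± 0.28), and Adgrl4 (1.32 ± 0.15). The clotting factor Vwf (3.47 ± 0.40) and the globin Hbb-bs (3.63 ± 0.18) rose. The class was a single cluster in which 8 of 12 stem/progenitor markers and 4 of 7 megakaryocyte markers met the naming limits. When clustered again, a cluster with its leading genes was named stem/progenitor-like (242, 351, 113 and 69 cells). The class may therefore mix both kinds of cell, and a different mix in the gates was not tested. Primary granule genes fell in 7 of 9 (−1.71, and −2.82 with free RNA subtracted), with Ctsg (−3.98 ± 0.22; 119, 159.7, 9.50 and 8.22 CPM), and Cpa3 (−4.45 ± 0.35) and Il1rl1 (−3.55 ± 0.44), both expressed in mast cells, fell. Secondary and tertiary granule genes rose in 10 of 14 (11 adjusted over the list alone; 2.68), with a median of 0.82 and no call once free RNA was subtracted. Markers used for the subtraction include members of that list, so its loss was partly fixed in advance. Ribosomal protein genes fell in 10 of 81 (50 adjusted over the list alone; −0.32). Camera called these 4 lists (adjusted p from 2.48e-16 to 8.92e-06; adjusted p from 0.303 to 0.502 with an estimated correlation). Of 9239 genes 563 passed, 367 higher and 196 lower, against 155 by DESeq2, 100 on thinned cells, 305 without ATTO high replicate 2 and 324 without ATTO low/negative replicate 1.

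Whether the gates differed by class was tested as an interaction with the immature neutrophil-like class, the largest. The response differed for 2976 of 12696 genes in monocyte-like, 3081 of 12209 in neutrophil progenitor-like, 2769 of 12119 in plasmacytoid dendritic cell-like, 1817 of 11667 in conventional dendritic cell-like, 1092 of 11141 in basophil/mast cell-like and 655 of 11329 in megakaryocyte-like cells (edgeR quasi-likelihood with a term per library). The clusters within the immature neutrophil-like class differed between the gates, and the interaction was not run on shared clusters. The counts may therefore in part reflect cluster mix. On simulated data for the monocyte-like comparison, the only one simulated, the interaction test recovered 76% of genes changed 2-fold, 60% of those changed 4-fold and 12% at the smallest change simulated, and 9 of 110 genes called were false. Only 200 genes were changed there, so these rates do not cover a shift of as many genes as were called.

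Fewer cells of the ATTO high gate were called in S phase. After thinning every cell to 3900 UMIs the share was 53% and 58% in ATTO low/negative and 10.3% and 7.51% in ATTO high over all cells, 35.0% and 41.5% against 7.63% and 7.10% in immature neutrophil-like cells, and 39.4% and 45.6% against 4.86% and 4.47% in monocyte-like cells. Neutrophil progenitor-like cells called G2M went from 25.2% and 26.5% to 42.4% and 40.8%. Each of these contrasts had an exact permutation p of 0.333, the smallest that n = 2 against 2 allows. In immature neutrophil-like cells the G2M share was 33.5%, 53.7%, 37.0% and 37.2% after thinning and 30.9%, 32.4%, 37.8% and 38.1% without it, so its direction turned with thinning and with ATTO low/negative replicate 2, without which the difference was 3.59 points. Thinning also left out shallow cells, so that 1045 of 1241, 1089 of 2262, 5410 of 5472 and 5113 of 5131 cells of the class remained. Free RNA enters such calls and differed between the gates, so no cycling was read from them alone.

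**Figure D3:**
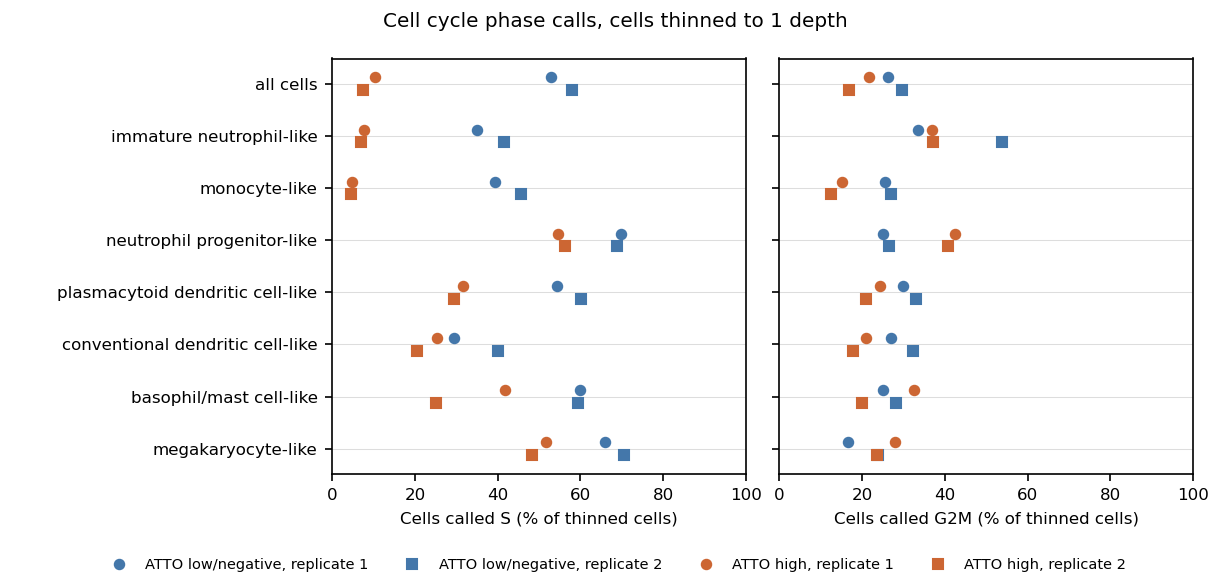
Share of cells called S (left) and G2M (right) by class after thinning to one depth (% of thinned cells), one point per library. Over all cells the S share is 53% and 58% in ATTO low/negative and 10.3% and 7.51% in ATTO high.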

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

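Of the tests below, those of depth for the S phase and the G2 and M phase genes were chosen only after the result was seen, and every other test was written before its own result but after the pattern itself.

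Neutrophil granule and maturation genes rose in ATTO high within classes that are not neutrophils. If free RNA of the library's neutrophils were the cause, a share estimated from one part of the neutrophil markers and subtracted should take the held-out part under 0.5 of its median, and it did in 5 of 5 classes (4 of 5 with the parts exchanged, the exception being basophil/mast cell-like cells with a ratio of 1.36). In the first direction too much was subtracted, as medians went past 0 in monocyte-like and basophil/mast cell-like cells (−2.43 and −2.52), and no counts were left for 4 of 9 markers in plasmacytoid and 5 of 10 in conventional dendritic cell-like cells, with only megakaryocyte-like cells above 0 (ratio 0.138), while in the exchanged direction only the monocyte-like median was at 0 and the ratio was 0.156 in plasmacytoid, 0.0141 in conventional dendritic and 0.255 in megakaryocyte-like cells. If doublets or misplaced neutrophils were the cause, the 5% of cells richest in these markers should carry most of their UMIs, and they did in both ATTO high libraries in 2 of 5 classes, conventional dendritic cell-like (56.4% and 50.8%) and megakaryocyte-like (67.3% and 59.7%), while in 1, monocyte-like, they carried less in both (21.2% and 20.4%). Free RNA and misplaced cells may both contribute, and how much each does stays open.

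Interferon response genes rose in ATTO high within the monocyte-like class. In cluster 2 alone the median was 0.165 of its value in the class (bootstrap over list members 0.0497 to 0.284). Cluster 21 of the class was itself led by such genes (Cxcl10, Ifit3 and Ifit1) and held 115, 136, 238 and 392 cells. Cluster 2 thus lacks those cells by construction, and the ratio does not decide between another mix of clusters and a response of the cells. With free RNA subtracted the ratio was 0.971 (0.962 to 0.989), an interval over list members that leaves out error in the subtracted share. That share rested on 11 and 12 markers in the ATTO low/negative and 20 in each of the ATTO high libraries. Estimated from one part of the neutrophil markers it was 8.31%, 6.81%, 11.98% and 12.23%, from the other 18.12%, 13.66%, 6.13% and 6.82%. Its order between the gates thus turned with the markers. At the share used most of the rise stayed, but other shares were not tried, so free RNA stays undecided. The source stays open, and no biological explanation was tested.

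S phase genes fell and G2 and M phase genes rose in ATTO high within the immature neutrophil-like class. For S phase genes, the ratio was 0.591 (0.543 to 0.875) in cluster 3 alone and 1.52 (1.39 to 1.90) on cells thinned to one depth. Neither depth nor the mix of clusters at this resolution therefore took away most of the fall. A mix of states within cluster 3 was not tested and cannot be excluded. In the finer clustering, cluster 11 (Ccne2, Esco2 and Rrm2 among its leading genes) held 313, 671, 543 and 398 cells. Cluster 3 of that clustering, also led by Syne2, held 51, 79, 1212 and 1243. For G2 and M phase genes, the ratio was 0.629 (0.426 to 0.836) in cluster 3 alone, an interval that spans 0.5, and cluster 17, led by Cenpf and Ube2c, is left out there by construction, so that cause stays undecided. On thinned cells it was −0.503 (−0.809 to −0.209), but the same cells at their own depth already gave 0.343 (0.167 to 0.459), so leaving out shallow cells took off most of the rise before thinning, and the part of deep cells in the summed counts stays open.

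The difference between the gates itself differed from that of immature neutrophil-like cells for 2976 genes in monocyte-like (2941 by limma voom), 3081 in neutrophil progenitor-like (2902), 2769 in plasmacytoid dendritic cell-like (2933), 1817 in conventional dendritic cell-like (1878), 1092 in basophil/mast cell-like (1081) and 655 in megakaryocyte-like cells (542). As clusters within the classes were not held constant, cluster mix may enter these counts, which was not tested. Barcodes over the mitochondrial limit numbered 1519, 302, 434 and 453, most of them in ATTO low/negative replicate 1, and were not used in the comparisons.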

How the results depend on the processing

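No test in this part was chosen only after the result was seen other than those on the best shared cluster, free RNA, reclustering, and lists on thinned cells or the same mix of clusters. Of 2958 values for the 208 named-gene results 2818 stayed the same, 130 were weaker, 4 stronger and 6 reversed. Of 824 list medians 719 stayed the same, 96 were weaker and 9 reversed, and of 118 class shares 101 stayed the same, 15 were weaker and 2 reversed. Counts of genes called stayed within 1.5-fold in 85 of 113, counts of lists in 63 of 77, counts of classes and clusters in 18 of 20, phase shares in 21 of 25 and interaction counts in all 6. Causes were not tested unless stated.

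With the same mix of clusters Nipbl stood at 0.0064, Pds5a reversed (0.0081) and 3939 genes passed over all cells. That draw evens the mix of clusters, not of states within them, and leaves 3927 cells per library. For example, monocyte-like clusters 2 and 4 of the finer clustering shared leading genes with cluster 2 of the main one. They held 107, 86, 1108 and 1334 cells and 901, 1102, 172 and 101 cells. DESeq2 called 1044 genes in basophil/mast cell-like, 1083 in conventional dendritic cell-like, 2000 in immature neutrophil-like, 155 in megakaryocyte-like, 3551 in neutrophil progenitor-like and 2779 in plasmacytoid dendritic cell-like cells. With coarser clusters 18 clusters differed, 3048 genes passed in neutrophil progenitor-like and 3056 in plasmacytoid dendritic cell-like cells, and the conventional dendritic cell-like share (0.082), Ube2c in that class (0.44) and Birc5 in monocyte-like cells (0.42) reversed; the cause was not tested. Clustered without the genes that differ within classes, 17 clusters differed and the megakaryocyte-like share reversed (4.88), as that name passed to a smaller set of 41 cells.

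In the best shared cluster alone 1021 genes passed in conventional dendritic cell-like, 1391 in immature neutrophil-like, 1816 in monocyte-like, 3420 in neutrophil progenitor-like and 1859 in plasmacytoid dendritic cell-like cells. Reversed there were Ccr7 (−0.053) and the G2 and M phase median (0.051) in conventional dendritic cell-like, that median in plasmacytoid dendritic cell-like (0.23), the lysosome median in immature neutrophil-like (−0.037) and the macrophage median in monocyte-like cells (−0.79); the cause was not tested. On thinned cells 6 lists and 2934 genes passed in neutrophil progenitor-like, 941 genes in basophil/mast cell-like and 100 in megakaryocyte-like cells, and Rad21 (−0.090), Sgo1 (−0.25) and the G2 and M phase median (−0.20) reversed in immature neutrophil-like cells. Without thinning the phase differences were 6.25 points for G2M and −23.6 for S in immature neutrophil-like and 17.6 for G2M in neutrophil progenitor-like cells. With free RNA subtracted 5 lists and 290 genes passed in megakaryocyte-like and 9 lists in plasmacytoid dendritic cell-like cells, and the inflammatory (−0.79), lysosome (−0.035) and maturation (−1.37) medians reversed in the former and the maturation median (−0.024) in the latter. The maturation list shares members with the markers used for the subtraction, so its change there was partly fixed in advance. With an estimated correlation 0 lists passed in all cells, immature neutrophil-like, monocyte-like, neutrophil progenitor-like, plasmacytoid dendritic cell-like, conventional dendritic cell-like, basophil/mast cell-like and megakaryocyte-like cells, and fry called 7 in conventional dendritic cell-like and 3 in megakaryocyte-like cells. The estimated correlation leaves few residual degrees of freedom, so its counts do not tell changed lists from unchanged ones.

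Replicate numbers are shared between the gates, but deviations of replicates correlated little (0.0578 over all cells, −0.0276 to 0.119 over the 8 sets of cells), so libraries were not paired. With a replicate block the shares of T, NK and innate lymphoid cell-like (2.62), immature neutrophil-like (1.52) and megakaryocyte-like cells (−1.20) no longer passed, and the best shared cluster with replicate block gave 1595 genes in immature neutrophil-like, 2193 in monocyte-like and 3611 in neutrophil progenitor-like cells. In that fit Mmp9 (4.77), Mmp8 (2.62), Gpr27 (2.06), Stfa2l1 (1.90), Slc7a11 (0.63) and Sgo1 (0.23) passed in immature neutrophil-like, Retnlg (3.26) and Mpo (−2.76) in monocyte-like and Ms4a6c (−1.12) in neutrophil progenitor-like cells, while Basp1 (1.46) in the first, Rsad2 (0.74), Ifit3 (0.56), Cdc6 (−0.92), Ccne2 (−0.64) and Nipbl (0.097) in the second and Irf8 (−1.18) and Ltf (2.03) in the third did not. Leaving out 1 library at a time, the counts of genes ran from 305 to 443 in megakaryocyte-like, 1160 to 1885 in basophil/mast cell-like, 485 to 2716 in conventional dendritic cell-like and 2224 to 3097 in immature neutrophil-like cells. Lists called ran from 5 to 8 in neutrophil progenitor-like cells, and the G2M difference in immature neutrophil-like cells from −16.6 to 3.59 points. Other tools for free RNA, doublets or integration were not run.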

Other observations

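Of the values in this part, those with the same mix of clusters, in the best shared cluster or with free RNA subtracted and the counts of markers that named a class were chosen only after the result was seen.

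The median of the ribosomal protein genes was below 0 in ATTO high in each of the 7 classes tested, though few members passed in megakaryocyte-like cells. The members lower numbered 79 of 83 in immature neutrophil-like, 77 of 83 in monocyte-like, 72 of 83 in neutrophil progenitor-like, 64 of 81 in plasmacytoid dendritic cell-like, 63 of 83 in conventional dendritic cell-like, 80 of 81 in basophil/mast cell-like and 10 of 81 in megakaryocyte-like cells. With the same mix of clusters 76 were still lower over all cells (median −0.27), so the mix of clusters at this resolution does not account for the direction. A mix of states within clusters was not evened out by that draw. With free RNA subtracted the class medians ran from −0.51 in basophil/mast cell-like to −0.17 in conventional dendritic cell-like cells, and camera still called the list lower in each. With an estimated correlation, a test with little power here, the list passed in none of the classes (adjusted p from 0.294 to 0.601). What lowers these transcripts was not tested.

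Markers that named a class were higher in ATTO high within it in 9 of 9 for conventional dendritic cell-like, 9 of 10 for monocyte-like, 5 of 8 with 2 lower for neutrophil progenitor-like, 4 of 10 with 1 lower for immature neutrophil-like, 4 of 10 for basophil/mast cell-like, 4 of 7 with 1 lower for megakaryocyte-like and 3 of 6 for plasmacytoid dendritic cell-like cells. Some of these rises depended on the cluster: in cluster 14 alone Ccr7 of conventional dendritic cell-like cells stood at −0.053 (4.74 in the class), and in cluster 2 alone the monocyte list had a median of 0.19 (0.67 in the class) and lost its call. Stem and early progenitor genes were also higher in plasmacytoid dendritic cell-like (9 of 11 with 1 lower, median 0.50 in cluster 10 alone) and megakaryocyte-like cells (7 of 15). Neither camera call held with an estimated correlation (adjusted p = 0.477 and 0.303), a test that passed no list in any class. The cluster named megakaryocyte-like itself carried stem/progenitor markers. The dye signal may follow cell type, size or uptake. The design used here has no cells without the guide, so an effect of NIPBL editing cannot be told from a difference in which cells take up or keep the dye.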
